A study of Rattus norvegicus with 6 samples.

How the data were processed

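RNA was sequenced from 6 samples of PC12 cells, 3 control and 3 with PCSK9 overexpression, grouped by their genotype labels. Per the labels' protocols, total RNA was extracted with TRIZOL, polyadenylated RNA was captured on beads, libraries were made with a kit that marks strand by dUTP, and 150 nt paired-end reads were sequenced on an Illumina NovaSeq instrument. TopHat2 2.0.4 is named in the submitters' processing notes. The counting tool, whether it used strand, the genome build and the annotation are not given in the sources used here, so no coordinates are printed beyond the chromosome that the tables give. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

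The authors' deposited read table holds whole-number counts per gene that are not normalized, for 18559 rat genes with Ensembl identifiers and symbols. The authors' deposited FPKM table holds 18522 of these genes as reads scaled to gene length and library size. In 3413 genes with an FPKM above 20 in every library, the 2 tables imply 1 length per gene to within a coefficient of variation of 0.265%, so FPKM adds a scaling by gene length and by total reads and no other correction. Total counts ran from 24879515 to 30820801 reads per library, at which 3 reads correspond to 0.0973 to 0.121 CPM. CPM (counts scaled to the library's total) were computed here from the counts, and per-gene SDs are of CPM. Reads shared between near-identical copies, overlapping genes or antisense partners may have been split or dropped in the authors' counting, which affects RT1, Oas and ribosomal protein genes and small RNAs.

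The counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test with TMM normalization, after filterByExpr with its default settings (count minimum 10) left 12107 genes. The genes left out held 0.0477% of the reads. Pcsk9 was among them, and its row was put back for its own test. Standard errors of log2 fold changes were taken from the fold change and the F statistic. P-values were adjusted by Benjamini-Hochberg and called under 0.05. The common dispersion corresponded to a biological coefficient of variation of 5.68%. Replicates of one group were compared by chi-square tests on genes with at least 20 reads in the pair, and the statistic per degree of freedom ran from 2.98 to 14.1, so no pair agreed within sampling noise and each library was counted once. Exact permutation tests of single values enumerate all splits of 3 against 3, whose smallest two-sided p is 0.1.

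The 30 gene lists, the named-gene rule and the alternatives were fixed before the data were examined. List symbols were matched to the symbols of the read table and, for 18 of 946, through other names of the same gene in a RefSeq gene table of assembly GRCr8, used for names only. 106 names had no match; 34 of the 946 are alternative spellings of the mitochondrial genes, of which 11 genes were matched. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Pcsk9 was left out of every list. A count "adjusted over the list alone" takes Benjamini-Hochberg over the list's tested genes.

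The rule for named genes was Pcsk9, then up to 12 genes per direction past the threshold with a mean log2 CPM of at least 1, coded as a mean of at least 2 CPM, and no overlap between groups, and up to 4 genes of smallest p in each list described. Placeholder names and pseudogenes were left out. Serpine1 was the gene that passed with a rise. No gene passed with a fall, and the rule's fallback to the 5 smallest p was read as applying to that direction: Fam162a, RNase_MRP, Ccnb1, Tpi1 and 7SK. Not every gene so named is printed. Cyr61, Tpm1, AY172581.9, AABR07015055.1, LOC100909555, Cryab, Sqstm1, Thbs1, Pgk1, Aldoc, Ddit4, Ldha, Ldlr, Vldlr, Lrp8, the RNA classes, and levels of cell type markers were chosen after their values were seen.

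The whole procedure was tested on counts simulated from the real means, depths and dispersions for 12107 genes, of which 240 were changed: 50 at each of 4 fold sizes, and the 40 genes of a raised list. For this comparison edgeR recovered 60% of 50 simulated genes changed 1.25-fold, 84% at 1.5-fold, 96% at 2-fold and 96% at 4-fold. It called 6 of the 40 list genes, and 6.45% of its 186 calls were false. Benjamini-Hochberg allows a larger p where more genes pass, and the real data gave 1 call. The cut-off there was stricter, so these rates do not give the power of the real comparison. The list of 40 genes, raised by 0.25 on the log2 scale, was recovered by camera with either correlation and by fry, with 0 false lists of the other 29. Each gene was simulated independently of the others, so this does not test how often lists of correlated genes are called falsely.

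The alternatives were RLE, upper-quartile and total-count scaling, 2 other filters on low counts, robust quasi-likelihood, DESeq2 1.42.0, limma-voom, limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, each library left out in turn, an adjusted p of 0.01, a 2-fold minimum and a test against a 1.2-fold change. Added after the data were seen were a covariate for the level of rRNA genes and the removal of control replicate 3 and PCSK9 replicate 1 together. Splicing was not analysed here, since the tables hold 1 value per gene.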

Results

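Polyadenylated RNA was sequenced from PC12 cells, a line derived from a rat adrenal pheochromocytoma, in a control group and in a group made to overexpress PCSK9, the secreted protein that directs LDL receptors to degradation. Each group held 3 libraries. The control libraries held 28529566, 29572730 and 24879515 reads on genes, and the PCSK9 libraries 29293298, 28546466 and 30820801. A single comparison followed from the design: which transcripts differ when PCSK9 is overexpressed. Of 18559 genes with reads, 12107 had enough reads to test.

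Pcsk9 (ENSRNOG00000006280, chromosome 5) was read first in every library. The control libraries held 3, 6 and 3 reads of the rat gene and the PCSK9 libraries 13, 10 and 10, so that all 3 PCSK9 libraries lay above all 3 control libraries. The means were 0.143 ± 0.053 CPM in control and 0.373 ± 0.063 CPM in PCSK9 (SD, n = 3 each). The ratio of pooled reads was 2.57, with an exact 95% interval of 1.30 to 5.47 that covers counting error only. An exact permutation test over the libraries, two-sided, gave p = 0.1, the smallest that 3 libraries against 3 allow. With its row kept in the edgeR fit, the log2 fold change was 1.33 ± 0.49 (SE), with an adjusted p of 0.741. The level stayed under 0.5 CPM in all 6 libraries, and the labels do not give the species of the transgene, whose reads would be counted here only as far as they align to the rat gene.

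Serpine1 (ENSRNOG00000001414, chromosome 12), which encodes plasminogen activator inhibitor, was the gene that passed the threshold over all genes. It rose from 78.0 ± 1.38 CPM in control to 100.1 ± 3.07 CPM in PCSK9 (SD, n = 3 each), a log2 fold change of 0.35 ± 0.044 (SE) with an edgeR adjusted p of 0.0198. Its 3 PCSK9 libraries lay above its 3 control libraries. No gene fell past the threshold, and no gene passed with a change of at least 1.5-fold. The genes next in rank, with an edgeR adjusted p of 0.0506 each, had log2 fold changes of 0.33 ± 0.051 for Cyr61, a matricellular protein, 0.23 ± 0.038 for the chemokine Ccl7, 0.23 ± 0.038 for the tropomyosin gene Tpm1 and 0.50 ± 0.082 for the 2'-5'-oligoadenylate synthetase Oas1a. On the lower side stood Fam162a, a mitochondrial protein gene induced by hypoxia, at 145 ± 2.72 CPM in control and 123 ± 1.17 CPM in PCSK9, with a log2 fold change of -0.25 ± 0.039 at the same adjusted p. The mitochondrial rRNA gene AY172581.9, at -0.42 ± 0.069, also had this adjusted p. Larger falls were seen in AABR07015055.1, from 694 ± 190 to 238 ± 138 CPM (-1.56 ± 0.29, edgeR adjusted p = 0.0693). LOC100909555 went from 4324 ± 1251 to 1757 ± 901 CPM (-1.31 ± 0.27, edgeR adjusted p = 0.111). Over 20 alternative settings the log2 fold change ran from -2.155 to -0.75 for AABR07015055.1, which passed in 8. For LOC100909555 it ran from -1.82 to -0.46, with a pass in 6. Like the rRNA class described below, both genes were highest in control replicate 3 and lowest in PCSK9 replicate 2. Whether they share a source with it was not tested. Ccnb1, which encodes cyclin B1, had a log2 fold change of -0.19 ± 0.040 and Tpi1, the triosephosphate isomerase of glycolysis, -0.28 ± 0.062, with adjusted p of 0.115 and 0.162.

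The test was edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 it held 732 genes, 371 higher and 361 lower, which is 6.05% of those tested, and 95 of them had a change of at least 1.5-fold. All 3 libraries of one group lay beyond the other's in 12.1% of the genes, against 10% by chance. DESeq2 called 31 higher and 9 lower genes, limma-voom 4 higher (Serpine1, Cyr61, Ccl7 and Tpm1) and 2 lower (Fam162a and the mitochondrial rRNA gene AY172581.9), and limma on log2(FPKM + 1) 0. With these tools 0 called genes reached 1.5-fold. Without control replicate 1, 2 or 3 edgeR called 0, 36 and 43 genes, and without PCSK9 replicate 1, 2 or 3 it called 2 (AABR07015055.1 and LOC100909555, both lower), 0 and 1 (AY172581.9, lower). Of these, 11, 5 and 2 reached 1.5-fold without control replicate 2, control replicate 3 and PCSK9 replicate 1. Serpine1 was not called without control replicate 1 (adjusted p = 0.132) or without PCSK9 replicate 1 (0.0614), 2 (0.0701) or 3 (0.122). Its log2 fold changes in these fits were 0.35, 0.34, 0.37 and 0.33 in that order.

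**Figure D1:**
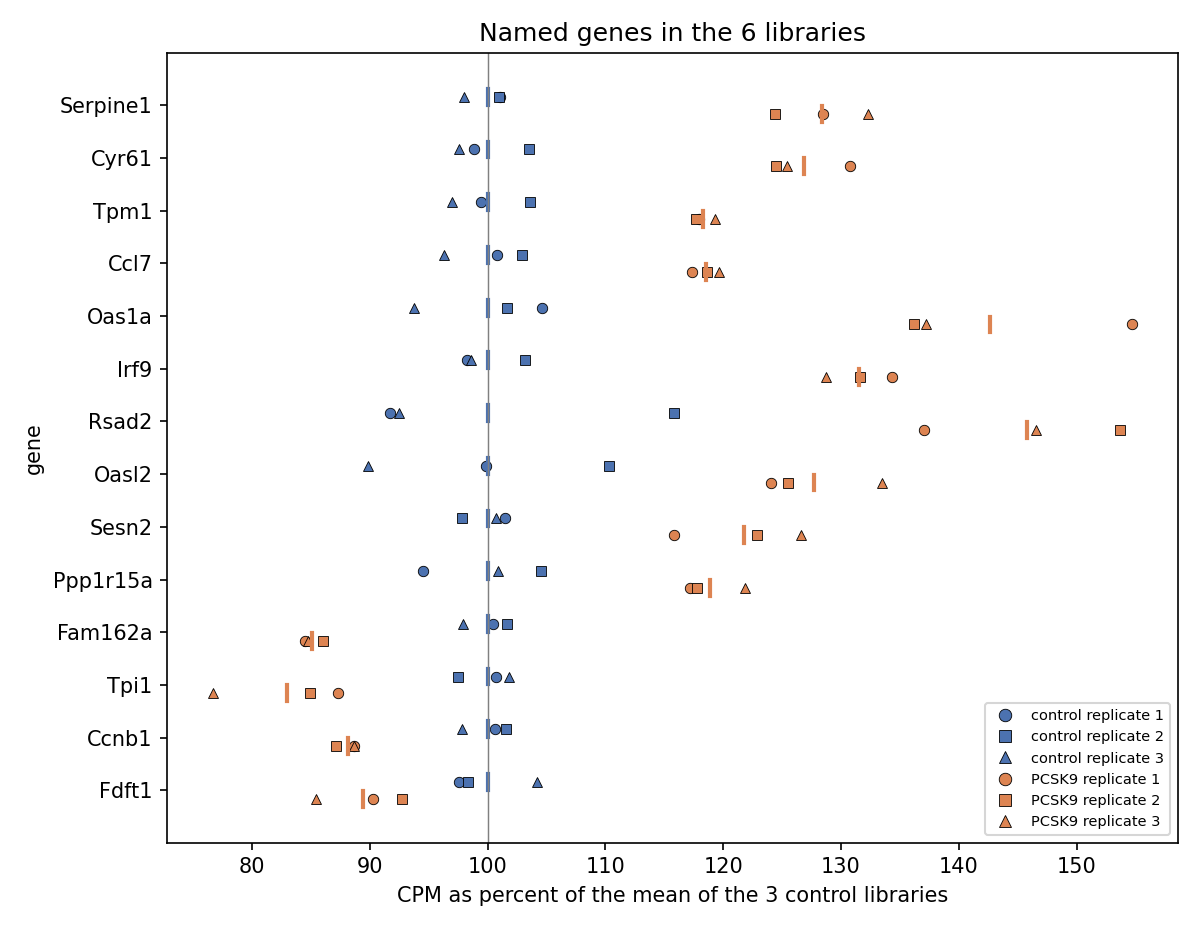
CPM of 14 named genes (vertical axis) in each library, as percent of the mean of the 3 control libraries (horizontal axis), with points for libraries and bars for group means. Serpine1, at 78.0 CPM in control and 100.1 CPM in PCSK9, is the gene past the threshold over all genes, and every PCSK9 library of each gene lies on one side of its control libraries. The genes were picked for small p-values, some also for groups without overlap, so this separation follows from the choice.

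The 30 gene lists fixed beforehand asked whether genes of known pathways shifted together. Camera with a preset inter-gene correlation of 0.01 called 15 of the 29 lists that could be tested, 8 toward higher and 7 toward lower expression in PCSK9. With the correlation estimated in each list, camera called 0 lists, with the smallest adjusted p at 0.0509, and 8 lists had an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 8. In every list the only member past the threshold over all genes was Serpine1, in the extracellular matrix list, so counts of single genes below are those adjusted over the list alone.

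The interferon-stimulated genes were shifted most. Of 44 tested, 43 were higher in PCSK9 and 21 rose when adjusted over the list alone, with a median log2 fold change of 0.21 (camera adjusted p = 2.33e-20; adjusted p = 0.0527 with an estimated correlation). Oas1a went from 13.5 ± 0.757 to 19.3 ± 1.41 CPM (SD, n = 3), and the antiviral gene Rsad2 from 13.9 ± 1.92 to 20.3 ± 1.16 CPM. Irf9, a subunit of the factor that drives these genes, had a log2 fold change of 0.38 ± 0.065. Oasl2 had a log2 fold change of 0.34 ± 0.062. These 4 genes had adjusted p between 0.0505 and 0.0693 over all genes. Oas1a and Oasl2 have close paralogs with which reads could be shared. Genes of antigen presentation by MHC class I were shifted the same way by less, with 21 of 25 higher, none past the threshold over the list alone and a median of 0.05 (adjusted p = 0.0146; adjusted p = 0.357 with an estimated correlation). RT1-A2 had a log2 fold change of 0.10 ± 0.051 and Tapbp, the tapasin gene, 0.11 ± 0.056, and reads of RT1 genes may be split among near-identical copies. The class I call was lost without control replicate 1 (median 0.03, adjusted p = 0.065), control replicate 2 (0.02, adjusted p = 0.205) or PCSK9 replicate 1 (0.03, adjusted p = 0.143), and with no filter on low counts (adjusted p = 0.054).

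Inflammatory genes under NF-kB were also shifted upward. Of 31 tested, 26 were higher and 6 rose when adjusted over the list alone, with a median of 0.12 (adjusted p = 6.8e-09; adjusted p = 0.0509 with an estimated correlation). The chemokine genes Ccl7, Cxcl1 and Ccl2 were among the 6, with 413 ± 14.1 and 489 ± 4.78 CPM for Ccl7, 400.4 ± 15.2 and 463 ± 12.2 CPM for Cxcl1, and 968 ± 69.7 and 1144 ± 41.3 CPM for Ccl2 in control and PCSK9 (SD, n = 3 each). Lif, a cytokine of the interleukin-6 family, had a log2 fold change of 0.39 ± 0.10.

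Stress response lists were shifted upward. In the unfolded protein and integrated stress response, 30 of 33 genes were higher and 6 rose when adjusted over the list alone, with a median of 0.06 (adjusted p = 1.91e-06; adjusted p = 0.0509 with an estimated correlation). Sesn2, a target of ATF4, had a log2 fold change of 0.27 ± 0.050, Ppp1r15a, which directs dephosphorylation of eIF2α, 0.24 ± 0.046, and the chaperone gene Dnajb9 0.38 ± 0.094. Among oxidative stress genes under NRF2, 19 of 26 were higher, 6 rose and 1 fell when adjusted over the list alone, with a median of 0.06 (adjusted p = 0.00676; adjusted p = 0.277 with an estimated correlation). Slc7a11, the cystine transporter, had a log2 fold change of 0.49 ± 0.12, the ferritin heavy chain Fth1 0.16 ± 0.045 and heme oxygenase Hmox1 0.13 ± 0.039. The NRF2 call was lost without control replicate 1 (median 0.056, adjusted p = 0.0866) or PCSK9 replicate 1 (median 0.071, adjusted p = 0.0635).

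Immediate early and ERK target genes, with 26 of 33 higher, and apoptosis and p53 targets, with 21 of 26 higher, were shifted upward with medians of 0.05 and 0.05 (adjusted p = 0.0166 and 0.0168; adjusted p = 0.135 and 0.227 with an estimated correlation). In neither list did a single gene pass when adjusted over the list alone. Dusp5, an ERK phosphatase, had a log2 fold change of 0.19 ± 0.070 and Klf10 0.12 ± 0.062, while the death receptor gene Fas had 0.19 ± 0.095 and Gdf15, a stress cytokine, 0.65 ± 0.24 at 0.879 and 1.39 CPM. The immediate early call was lost without control replicate 1 (adjusted p = 0.0866), control replicate 2 (0.0555) or PCSK9 replicate 1 (0.0804), and the apoptosis call without control replicate 1 (0.303), control replicate 2 (0.0997) or PCSK9 replicate 2 (0.0669). In that order the medians were 0.043, 0.055 and 0.056 for immediate early genes and 0.038, 0.037 and 0.032 for apoptosis genes. With the rRNA level as a covariate both calls were lost (0.0597 and 0.0593), and without control replicate 3 the apoptosis median was 0.08.

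Hypoxia-response genes were shifted downward. Of 39 tested, 31 were lower in PCSK9 and 8 fell when adjusted over the list alone, with a median of -0.10 (adjusted p = 6.8e-09; adjusted p = 0.112 with an estimated correlation). The 8 were Tpi1, Higd1a, Gpi, Hk2, Pgk1, Aldoc, Ddit4 and Ldha. Tpi1 went from 52.0 ± 1.17 to 43.2 ± 2.90 CPM, Gpi, glucose-6-phosphate isomerase, from 1388 ± 58.0 to 1231 ± 29.3 CPM, and Hk2, hexokinase, from 77.6 ± 2.68 to 69.6 ± 0.885 CPM (SD, n = 3 each). Higd1a, a mitochondrial protein gene induced by hypoxia, had a log2 fold change of -0.18 ± 0.041.

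Genes of cholesterol synthesis, which SREBP2 controls, were shifted downward, with 23 of 24 lower and a median of -0.10 (adjusted p = 2.46e-07; adjusted p = 0.0509 with an estimated correlation). None passed when adjusted over the list alone. Fdft1, squalene synthase, had a log2 fold change of -0.17 ± 0.049, Fdps -0.15 ± 0.046, Mvk -0.20 ± 0.069 and Dhcr7 -0.15 ± 0.053. The LDL receptor family and lipoprotein uptake list was not called, with 10 of 17 lower (adjusted p = 0.553). Ldlr itself, chosen after its values were seen, stood at 185 ± 3.68 CPM in control and 173 ± 7.66 CPM in PCSK9 (adjusted p = 0.782), with the 3 PCSK9 libraries below the 3 control libraries. Vldlr and Lrp8, chosen in the same way and related receptors that PCSK9 also binds, had log2 fold changes of -0.07 ± 0.11 and 0.08 ± 0.047. The lists of cholesterol efflux (adjusted p = 0.864) and fatty acid synthesis (0.502) were not called.

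Cell cycle and DNA replication genes were shifted downward by less, with 34 of 44 lower, Ccnb1 alone falling when adjusted over the list alone, and a median of -0.05 (adjusted p = 0.000217; adjusted p = 0.126 with an estimated correlation). Gins2 had a log2 fold change of -0.17 ± 0.054, Tk1 -0.15 ± 0.048 and Kif20a -0.11 ± 0.038. Cytosolic ribosomal proteins, with 50 of 58 lower, and nuclear-encoded oxidative phosphorylation, with 40 of 49 lower, had medians of -0.04 and -0.04 (adjusted p = 0.00132 and 0.00177; adjusted p = 0.68 and 0.591 with an estimated correlation). No gene of either passed over the list alone, with log2 fold changes of -0.07 ± 0.041 for Rpl19, -0.10 ± 0.045 for Rps19, -0.11 ± 0.042 for Uqcrh and -0.10 ± 0.040 for Cox6c. Reads of ribosomal proteins may be shared with their pseudogenes. Without control replicate 3 both calls were lost, at adjusted p of 0.994 for ribosomal proteins, whose median was then 0.0065, and 0.622 for oxidative phosphorylation, with a median of -0.011. With the rRNA level as a covariate they were also lost, with medians of 0.0069 and 0.0091 (adjusted p = 0.554 and 0.678). MHC class II genes, 7 of 8 lower, had a median of -0.10 (adjusted p = 0.00443; adjusted p = 0.126 with an estimated correlation), and complement genes, 7 of 8 lower, a median of -0.05 (adjusted p = 0.0427; adjusted p = 0.238 with an estimated correlation). Cd74, the invariant chain, stood at 6.82 ± 0.584 CPM in control and 5.31 ± 0.464 CPM in PCSK9, and C3 at 22.3 ± 0.161 and 20.5 ± 0.0965 CPM. RT1-Bb had a log2 fold change of -0.77 ± 0.37 and C1s -0.11 ± 0.051. The MHC class II median was -0.06, -0.15 and -0.06 without control replicate 1, 2 and 3, and the call was lost with no filter on low counts (median -0.02, adjusted p = 0.582) and with the rRNA covariate (-0.0012, adjusted p = 0.182). The complement call was lost without control replicate 1, 2 or 3 (medians -0.02, -0.08 and -0.05, adjusted p = 0.263, 0.0676 and 0.0646) or PCSK9 replicate 1 (-0.02, adjusted p = 0.697), and the list passed in 8 of 19 alternative settings, with a median of -0.10 without PCSK9 replicate 2 and -0.10 without PCSK9 replicate 3.

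**Figure D2:**
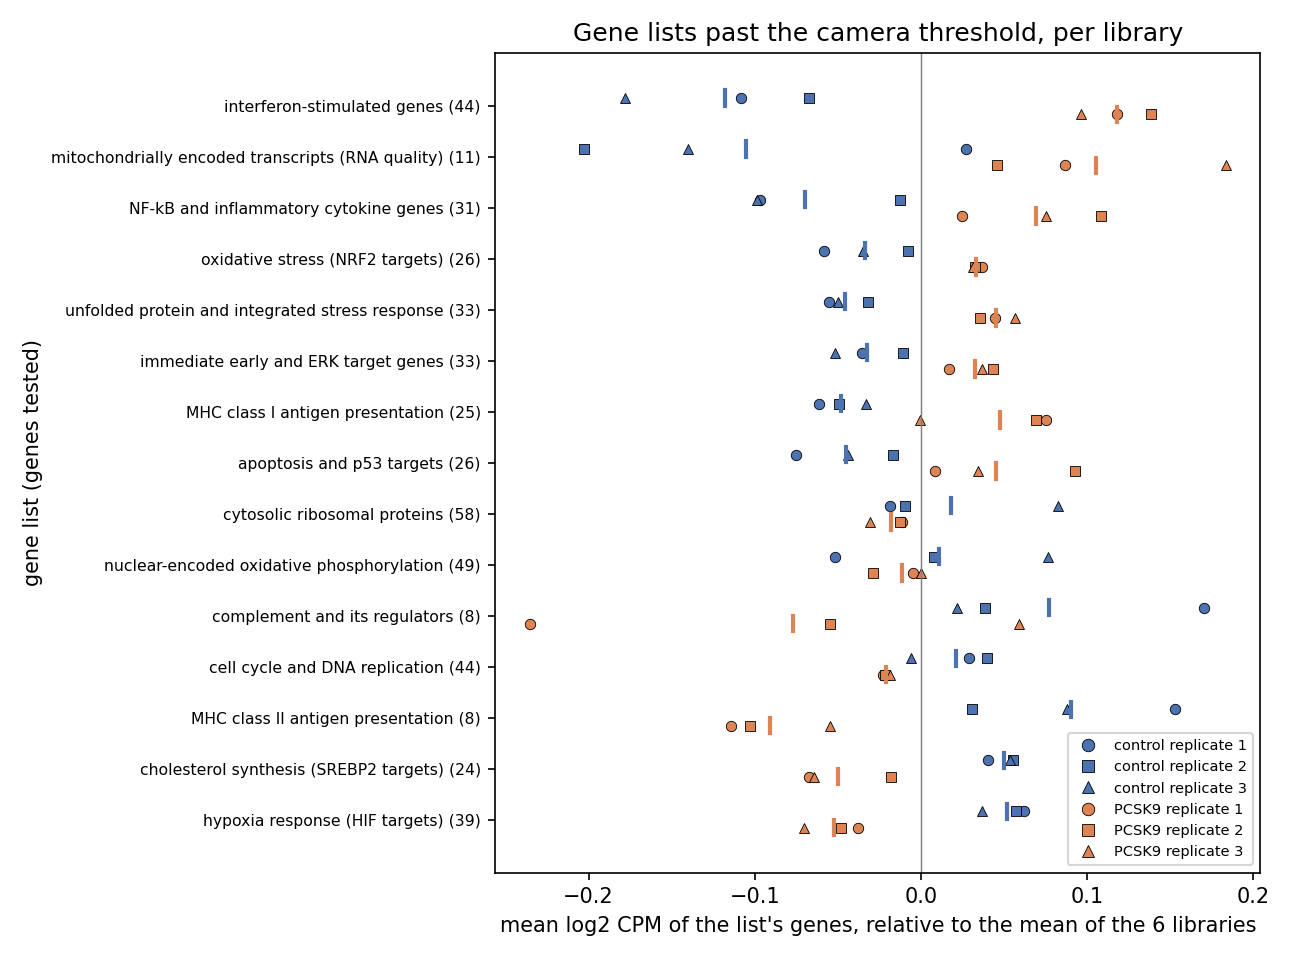
Mean log2 CPM of each called list's genes relative to the mean of the 6 libraries (horizontal axis), per list (vertical axis, genes tested in parentheses), with points for libraries and bars for group means. Interferon-stimulated genes lie between 0.10 and 0.14 in the PCSK9 libraries and between -0.18 and -0.07 in the control libraries, while ribosomal protein and oxidative phosphorylation genes stand apart mainly in control replicate 3.

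All 11 mitochondrially encoded transcripts tested were higher in PCSK9, with 6 rising when adjusted over the list alone and a median of 0.15 (adjusted p = 2.42e-05; adjusted p = 0.277 with an estimated correlation). Mt-nd5 went from 1318 ± 177 to 1694 ± 144 CPM. Of the 6 classes of structural RNA, which carry no long poly(A) tail, all 6 had a lower mean in PCSK9, and in 2 of them, ribozyme and snoRNA genes, the groups did not overlap. Without control replicate 3 the scaRNA mean was higher in PCSK9, at a ratio of 1.09. Genes of the rRNA class summed to 49.9 ± 27.0 CPM in control and 21.2 ± 12.3 CPM in PCSK9 (exact permutation p = 0.2), ribozyme genes to 16.8 ± 5.33 and 7.05 ± 3.28 CPM (exact permutation p = 0.1), and snoRNA genes to 33.9 ± 1.57 and 31.2 ± 1.48 CPM (exact permutation p = 0.1), with n = 3 per group and two-sided tests. The groups overlapped for rRNA, misc RNA (8.15 ± 2.16 and 4.33 ± 2.73 CPM, exact permutation p = 0.2), snRNA (34.1% lower in PCSK9, exact permutation p = 0.3) and scaRNA genes (1.48 ± 0.425 and 1.35 ± 0.162 CPM, exact permutation p = 0.9). Sums without overlap were also lower for mitochondrial rRNA, at 467 ± 37.1 and 351 ± 42.3 CPM (exact permutation p = 0.1) and histone genes, at 55.0 ± 5.23 and 46.0 ± 1.21 CPM (exact permutation p = 0.1). RNase_MRP, the RNA of a ribonuclease, had a log2 fold change of -1.50 ± 0.28 (adjusted p = 0.0693) and 7SK, a small nuclear RNA that restrains transcription elongation, -1.29 ± 0.30 (adjusted p = 0.202). Control replicate 3 had the highest rRNA level, 80.7 CPM, and the lowest depth, and it lay farthest from the others on the first principal component. That component held 31.2% of the variance and did not separate the groups. Control replicate 2, at 11.0, lay beyond the PCSK9 libraries, at -0.398, 6.325 and 8.63.

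Markers of chromaffin cells were mostly near 0 in both groups. Of the 35 chromaffin and catecholamine genes listed, 27 were under 1 CPM or had no matching row. Th, tyrosine hydroxylase, stood at 0.0882 ± 0.0654 CPM in control and 0.274 ± 0.158 CPM in PCSK9, the granule protein gene Chga at 0.0363 ± 0.00338 and 0.179 ± 0.070, and Dbh, dopamine β-hydroxylase, at 0.345 ± 0.125 and 0.398 ± 0.122. The other 8 were Scg2, a secretogranin, at 414 ± 49.9 and 435 ± 20.3 CPM, Pam at 127 ± 8.91 and 127 ± 5.10 CPM, and, as means of the 6 libraries, Comt at 123, Cpe at 76.6, Maoa at 39.1, Pcsk2 at 17.4, Gata2 at 1.13 and Cyb561 at 1.05 CPM. Of the 11 Schwann and glial genes listed, 4 were above 100 CPM and 4 were under 1 CPM or had no matching row. Sox10 stood at 644 ± 27.6 and 652 ± 13.5 CPM and S100b at 234 ± 2.01 and 239 ± 9.30 CPM, and Erbb3 and Pmp22 had means of 119 and 179 CPM. The myelin genes Mbp, Mpz and Plp1 had means of 0.093, 0.914 and 4.69 CPM, Cdh19 5.77 and Gfap 9.16 CPM. Of the 14 fibroblast and mesenchymal genes listed, 3 were above 100 CPM and 7 were under 1 CPM or had no matching row. Pdgfra stood at 203 ± 16.7 and 196 ± 3.56 CPM (SD, n = 3 each throughout). Vim and Fbln1 had means of 4380 and 160 CPM, and Col1a1 and Acta2 of 0.94 and 0.37 CPM. Of the chromaffin list, 11 genes could be tested and the list was not called (adjusted p = 0.267), nor were those of Schwann and glial (0.897), fibroblast (0.915), endothelial (0.586) and leukocyte (0.553) markers.

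**Figure D3:**
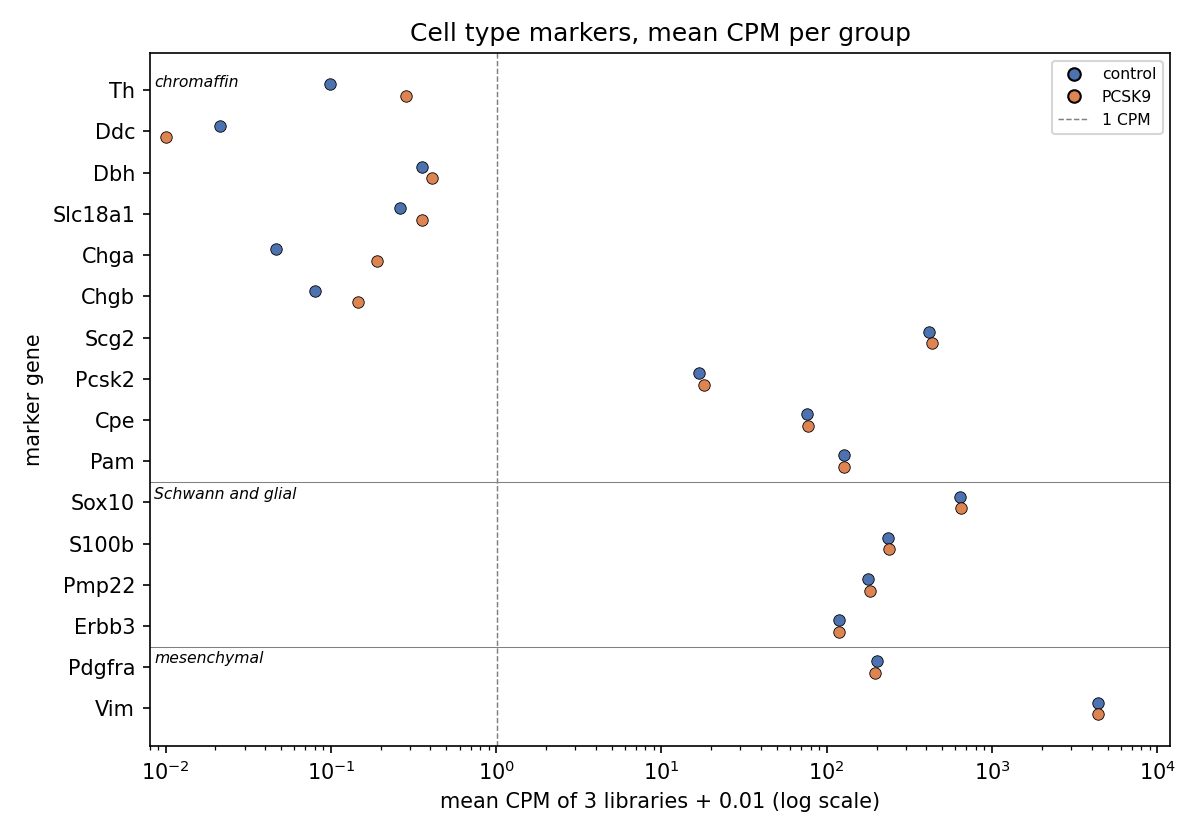
Mean CPM of the 3 libraries per group plus 0.01, on a logarithmic horizontal axis, for chromaffin, glial and mesenchymal marker genes (vertical axis), with a dashed line at 1 CPM. Th, Ddc, Dbh, Slc18a1, Chga and Chgb lie under 1 CPM in both groups, while Sox10, at 644 CPM in control, S100b, Pmp22 and Erbb3 lie above 100.

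The lists left with no call also held splicing factors, with 38 of 51 genes higher and a median of 0.03 (adjusted p = 0.0887), synaptic release and ion channel genes (0.477), neuronal cytoskeleton genes (0.889), lysosome and endocytosis genes (0.774), extracellular matrix and adhesion genes (0.553) and heat shock genes (0.27). Splicing factors were called in 3 of 19 alternative settings, with DESeq2, with limma-voom and without control replicate 2 (median 0.07, adjusted p = 0.0125), and over the settings their adjusted p ranged up to 0.894. Heat shock genes were called with DESeq2 and leukocyte markers with the rRNA covariate, each in 1 setting. Adjusted over the list alone, Cryab rose among the heat shock genes, Sqstm1 among the lysosome genes, and Serpine1 and Thbs1 among the matrix genes. The mean log2 fold change of the heat shock genes was -0.02 against a median of 0.03, and that of the LDL receptor family 0.02 against -0.03. Without 1 library the median of the heat shock genes ran from -0.00033 (control replicate 3) to 0.11 (control replicate 2), and that of the LDL receptor family from -0.05 (PCSK9 replicate 2) to -0.01 (PCSK9 replicate 1). In the lysosome, neuronal cytoskeleton and fibroblast lists the median was below 0 (-0.0031, -0.0093 and -0.013) while camera's direction was up, and for Schwann and glial markers the mean was below 0 (-0.04). Adrenal cortex markers had too few tested genes for a test.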

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

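The tests with the rRNA covariate and with control replicate 3 and PCSK9 replicate 1 removed together were chosen only after the result was seen. Serpine1 kept its direction in all 20 settings and passed in 13, and 7 of the 15 called lists passed in all 19 settings that refit them: interferon-stimulated, NF-kB, unfolded protein response, mitochondrially encoded, hypoxia, cholesterol synthesis and cell cycle. These 19 settings keep the preset correlation. Of the 7 lists, fry called all but the mitochondrially encoded one (fry adjusted p = 0.1615). The counts of genes were unstable. RLE size factors, total counts without TMM and a filter of CPM of at least 1 in 3 libraries called Serpine1 alone, like the main fit. Upper-quartile scaling called 14 genes (9 higher, 5 lower, 2 of at least 1.5-fold), robust quasi-likelihood 10 (9 and 1), DESeq2 40 (31 and 9), limma-voom 6 (4 and 2) and limma on FPKM 0 with log2(FPKM + 1), 0 with log2(FPKM + 0.1) and 0 with a mean FPKM of at least 1, so 0 higher. With no filter on low counts edgeR called 104 (65 and 39, 33 of at least 1.5-fold), with a prior of 1185 degrees of freedom against 10.1, which pulls each gene's spread almost wholly to the trend. The replicate block gave 10 (4 and 6, 5 of at least 1.5-fold) and 14 lists, the complement list being lost with the block (adjusted p = 0.0737). The same-number libraries' deviations correlated at -0.116, 0.297 and -0.248, which gives no sign that the numbers pair the libraries. Pairs of different number ran from -0.488 (control replicate 2 with PCSK9 replicate 1) to 0.479 (control replicate 3 with PCSK9 replicate 1). So few pairs cannot exclude a shared day or batch. The rRNA covariate gave 29 (14 and 15, 3 of at least 1.5-fold), and the joint removal 58 (36 and 22, 11 of at least 1.5-fold). An adjusted p of 0.01 called 0 genes. Leaving out 1 library at a time gave 0 to 43 genes, 0 to 33 higher, 0 to 12 lower and 0 to 11 of at least 1.5-fold. Camera with an estimated correlation called 0 lists and fry 8. Apart from the filter, the cause was not tested.

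The log2 fold change of Pcsk9 stayed above 0 wherever it could be had. It was 0.09 on log2(FPKM + 1), a scale that shrinks low genes, and no row was left with a mean FPKM of at least 1. DESeq2 gave no adjusted p for it or for 13 other named genes. Of the lists that were not called, several turned in camera's direction, which can differ from the sign of the median; the values given are medians at those settings. For cholesterol efflux they were -0.0040 with CPM of at least 1, 0.0021 with DESeq2, 6.5e-05 with voom, 0.0081 with log2(FPKM + 1), 0.0042 with a mean FPKM of at least 1, -0.019 without control replicate 2 and -0.037 without PCSK9 replicate 1, with 0.019 at most without 1 library. Fibroblast markers gave -0.011 with no filter, -0.014 with CPM of at least 1, -0.014 with DESeq2, -0.013 with voom, -0.0040 with a mean FPKM of at least 1, 0.014 without control replicate 3, -0.027 without PCSK9 replicate 1, -0.0048 in the joint removal and -0.11 with the rRNA covariate. Schwann and glial markers gave 0.0068 with no filter, 0.0085 with the replicate block, -0.0049 without PCSK9 replicate 1 and 0.014 without PCSK9 replicate 2, with 0.036 at most without 1 library. Neuronal cytoskeleton genes gave -0.014 with CPM of at least 1, -0.0071 with the replicate block, and -0.021, -0.022 and -0.0025 without control replicate 1, control replicate 2 and PCSK9 replicate 1, with 0.044 at most without 1 library. Without control replicate 2 and PCSK9 replicate 1, lysosome genes gave -0.019 and 0.0016, matrix genes -0.0045 and -0.019, and leukocyte markers 0.012 and -0.016. The highest values without 1 library were 0.027 for matrix genes, 0.28 for leukocyte markers and 0.066 for splicing factors. Matrix genes gave -0.0082 in the joint removal. Splicing factors gave 0.00033 without control replicate 3 and -0.027 with the rRNA covariate. With that covariate the called lists of oxidative phosphorylation and ribosomal proteins turned to 0.0091 and 0.0069, heat shock genes to -0.054, RT1-Da to 0.0024, Casp12 to -0.040, Egr3 to -0.20 and Ndufs8 to 0.0023. Vldlr turned to 0.072 without control replicate 2 and was -0.18 at the lowest without 1 library. At a depth of 24879515 to 30820801 reads, Pcsk9 had 3 to 13 reads per library, which limits the precision of its fold change.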

Other observations

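The top-ranked genes held known targets of YAP/TAZ, TGF-beta and SRF and of the amino acid response under ATF4. Lists of these targets were written after the top genes were seen, and each was tested without the 50 genes of smallest p. Predictions for these 4 lists, for RNA polymerase III and for control replicate 3 as the source of the rRNA difference were made before their tests. Leaving out each library in turn was planned, while reading the lower quartile of the interferon list from it, the splits, the rRNA covariate, the counts of RNA classes, with and without control replicate 3, and the tests on chromaffin genes were tests chosen only after the result was seen.

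The ATF4 targets were higher in 26 of 33 genes, with a median log2 fold change of 0.08 (camera adjusted p over the 4 lists = 3.9e-05; adjusted p = 0.109 with an estimated correlation), so the call rests on the preset correlation, and 8 of its genes are also in the stress response list of the report. YAP/TAZ targets were higher in 13 of 20 (adjusted p = 0.0924), TGF-beta targets in 15 of 23 (0.0895) and SRF and actin targets in 11 of 16 (0.0895), and none of these lists passed. Whether the rise of Serpine1 belongs to a wider programme of one of these factors may still be asked, and these data do not settle it.

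The number of other groupings limits what can be said of chance. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1 gene and the highest other split 42, and 5 of the 10 splits called at least as many as the real one. That other split set control replicates 1 and 3 with PCSK9 replicate 1 against the rest. In it 1996 genes had an unadjusted edgeR p under 0.05, against 732 in the real split. These 3 libraries also held the most rRNA, at 38.8, 80.7 and 35.1 CPM, against 11.7 to 30.2 CPM in the rest. Misc RNA and snRNA divided the libraries in the same way. The 42 genes, 38 of them protein-coding, included Y_RNA, U1, U4 and 5S_rRNA. This points to a structure beside the groups that ran with these RNAs, whose means were also lower in PCSK9. Its cause was not tested. For lists, camera with the preset correlation called 15 in the real split and 1 to 6 in every other split. Of the 10 splits, 1, the real one, reached 15. Fry called 8 lists in the real split and 0 in every other.

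The higher interferon-stimulated genes were weighed against RNA composition and against single libraries. With the rRNA level as a covariate, the median of the list went from 0.21 to 0.15 and the lower quartile to 0.064. Of 44 genes, 37 were higher (camera adjusted p = 3.17e-09). Across the 19 settings the camera adjusted p with the preset correlation ranged from 2.19e-34 to 3.17e-09. The rRNA class, of 13 genes, is a single and imperfect measure of carry-over, and an adjustment for it can leave carry-over in part uncorrected. A shift was thus left beyond this measure, but the fit cannot exclude carry-over as its cause. With an estimated correlation and no covariate the call was lost (adjusted p = 0.0527). Leaving out each library in turn, the lower quartile of the list was never under 0.089, which argues against 1 deviating library. PCSK9 itself, the construct or its delivery, and a difference between cultures may each account for the shift and are confounded in this design, so no biological explanation was tested apart from them.

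The lower level of RNAs without a poly(A) tail may come from less carry-over of such RNA through the poly(A) capture. All 6 classes of structural RNA had a lower mean in PCSK9, scaRNA only with control replicate 3 included, and in 2 of the 6 every PCSK9 library lay below every control library. Lower output of RNA polymerase III would spare the U1, U2, U4 and U5 RNAs, which polymerase II makes. Their ratio of PCSK9 to control was 0.608. U6 and 5S rRNA, which polymerase III makes, fell further, at a ratio of 0.437 (50.6 ± 26.8 and 22.1 ± 12.3 CPM). In both sets the libraries of the groups overlapped, so these ratios do not separate the explanations. Ribozyme, snoRNA, mitochondrial rRNA and histone genes were taken up again without control replicate 3 because their groups did not overlap over all 6 libraries. Every PCSK9 library therefore had to lie below both other control libraries, so this order cannot weigh control replicate 3 alone as their source. Without control replicate 3 the means were apart by more than the larger SD in 4 of these 4 classes. The ratios of PCSK9 to control were 0.513, 0.942, 0.738 and 0.884 in that order. For rRNA genes the ratio was then 0.615 with overlapping groups, so control replicate 3 alone and a difference between the groups cannot be told apart there.

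The low level of most chromaffin genes was weighed against counting and admixture. Of the list, 77.1% was under 1 CPM or unmatched, against at most 15% in the splicing, lysosome, oxidative phosphorylation, ribosomal and cell cycle lists, which argues against reads missed by the counting at large. Th, Chga and Dbh reached at most 0.49 CPM in any library, which argues against glial cells as a minority in a chromaffin culture. Sox10 and S100b were never under 231.5 CPM, although Mbp and Mpz had means of 0.093 and 0.914 CPM. A culture without the chromaffin programme remains a candidate explanation in both groups alike. Its prediction restates the levels already seen, so these values do not test it. Whether such cells lost that programme or are of another origin cannot be told apart here, since no value in the tables decides it.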
